A study of Mus musculus with 8 samples.

How the data were processed

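RNA from perfused hearts of 4 LPS-treated and 4 saline-treated mice was extracted, amplified to biotin-labelled cRNA and hybridised to 8 spotted mouse long-oligonucleotide arrays. Groups, gene lists, tests, thresholds, alternatives and the rule for naming genes were set before the data were examined. Per the file headers, the scanner files hold spot and local background intensity at 635 nm, without normalization or background subtraction, exported by GenePix Pro 4.1.1.4 from a GenePix 4000B scanner (gain 650, pixels of 5 µm). The deposited value table is on a log2 scale; its values are log2 of background-subtracted medians, set to 1 where lower, plus 1 shift per array, as read from the values themselves. How the authors made that table is not given in the sources used here. Its probe identifiers matched 0 of those in the scanner files and carried no gene names, so all gene results came from the scanner files.

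Median spot intensities were background-corrected by the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, taken to log2 and quantile normalized. Spots that the scanner software marked bad were treated as missing. A spot counted as above background where its signal minus local background exceeded the 95th percentile of that array's 94 negative-control spots, a class read from the identifier prefix. The software's own mark for spots not found was absent on LPS 2 and was not used. Of 35078 gene probes, 23071 matched 1 gene symbol through their RefSeq accession and 12007 matched none. Probes above background on at least 4 of the 8 arrays were kept (14915), and the brightest probe stood for each gene, giving 8875 genes and 3226 unnamed probes.

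LPS was compared with saline by the moderated linear model of limma, with Benjamini-Hochberg adjustment over all tested genes and probes and a threshold of 0.05. The prior contributed 4.13 of 10.13 degrees of freedom. Values are log2 LPS minus saline with the standard error of the model. The offset of 50 shrinks the changes of dim genes. With an offset of 16, 506 genes were called at least 2-fold higher and 289 at least 2-fold lower, against 414 and 179. Where a gene was above background on no array of a group, its change is given as a bound. The bound raises the gene's value on each dim array to the lowest normalized value of any probe above background on that array, takes the difference from the mean of the other group, and is written as at least that many fold. There were 59 such called genes dim in saline and 46 dim in LPS. Groups of genes were tested by camera with a preset correlation of 0.01, adjusted over 30 lists, and again with an estimated correlation and by fry. The estimated correlation of the oxidative phosphorylation list was 0.009, below the preset value. Its unadjusted camera p still rose from 0.00452 to 0.0287, so these forms of camera differ in more than the correlation.

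The lists were cytokines and chemokines, Toll-like receptor and NF-kB signalling, interferon-stimulated genes, interferon-gamma genes, acute phase and metal binding, fatty acid oxidation, PPAR and PGC-1 regulators, oxidative phosphorylation, tricarboxylic acid cycle and branched-chain amino acids, glycolysis, sarcomere, calcium handling and ion channels, cardiac stress, beta-adrenergic and nitric oxide signalling, and AP-1 and MAP kinase. The others were endothelial activation, endothelial identity, neutrophil, monocyte and macrophage, lymphocyte, fibroblast and matrix, smooth muscle and pericyte, erythroid and platelet, atrial, adipocyte, circadian, glucocorticoid-responsive, oxidative and ER stress, autophagy and cell death, and cell cycle. Some genes belong to more than 1 list. Genes named with values are, first, the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap. Genes above background on no array of a group were left out there and ranked by bound, the 5 largest being named. Also named are the 2 largest called rises and falls of each list (or its smallest p). The rest are a set of cytokine, LPS receptor, lipid metabolism, adrenergic and cardiac genes. Members named only by symbol beside a count of 6 or fewer were chosen after their values were seen.

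The median signal over background was 18, 15, 16 and 12 intensity units on LPS arrays 1 to 4 and 32, 19, 15 and 18 on saline arrays 1 to 4, against negative-control limits of 25.9 to 40.5. In 5 runs on simulated data with 200 changed genes among 8875, the procedure called 27.4% of genes changed 1.5-fold, 89.0% of those changed 2-fold and 99.4% of those changed 4-fold. Of its calls 5.14% were unchanged genes. The simulated noise was independent between genes and was added after background correction and filtering, and fewer genes changed than were called here. These rates may therefore not carry over to the real arrays. Alternatives covered background correction, offset, normalization, dim-probe filter, probe choice, prior, array weights, test, scan day, a redip mark whose meaning is not given in the sources used here, slide series, replicate number as a block, leaving out each array, and the deposited value table. Alternatives chosen after seeing the data were the mean spot intensity, leaving out LPS 3 with saline 1, arrays with or without the redip mark alone, the second slide series alone, an atrial covariate, and median scaling over the tested probes.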

Results

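The series measured messenger RNA in the mouse heart after lipopolysaccharide (LPS), the cell-wall component of Gram-negative bacteria that triggers systemic inflammation. Female C57BL/6 mice, an inbred laboratory strain, aged 12 weeks received 5 mg/kg LPS (4 mice) or saline (4 mice) into the peritoneum, and the hearts were perfused and taken 8 h later. RNA from pieces of each heart was hybridised to a spotted 1-colour oligonucleotide array, giving 8 arrays from 8 separate mice. Most gene probes stayed near background. Between 37.3% and 42.6% of them exceeded the negative-control limit on the LPS arrays, and between 39.7% and 46.9% on the saline arrays. The median signal over background was 12 to 18 intensity units on the LPS arrays and 15 to 32 on the saline arrays, against a local background of 38 to 40. After filtering, 8875 named genes and 3226 probes without a name were tested.

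The comparison asked which cardiac transcripts differed 8 h after LPS. The largest rises were in acute phase proteins and chemokines. Saa3, an acute phase serum amyloid, rose by a log2 change of 8.66 (SE 0.33, adjusted p = 6.48e-07), from 6.66 ± 0.58 (SD, n = 4, above background on 2 saline arrays) to 15.32 ± 0.57 (n = 4). Lcn2, an iron-siderophore binding protein of innate immunity, rose by 7.18 (SE 0.33, adjusted p = 1.5e-06), from 7.67 ± 0.60 to 14.85 ± 0.56. The largest fall was in Tcf15, a transcription factor of heart endothelium and muscle, whose log2 change was -3.03 (SE 0.36, adjusted p = 0.000467), from 10.15 ± 0.28 to 7.13 ± 0.86.

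Of the 8875 genes, 1731 (19.5%) passed an adjusted p of 0.05 in limma, 864 higher and 867 lower with LPS. At least 2-fold changes were more frequent upward after quantile normalization, in 414 genes against 179 downward. Cyclic loess gave the same direction (448 and 145). Median scaling of each array over all gene probes, most of them near background, reversed it (260 upward and 519 downward). Median scaling over the tested probes, chosen after the data were seen, gave 435 upward and 194 downward. The neutrophil-attracting chemokines Cxcl5 and Cxcl1 rose by 6.48 (SE 0.56) and 5.00 (SE 0.31) on the log2 scale, and the interferon-inducible chemokines Cxcl9 and Cxcl10 rose by 6.38 (SE 0.41) and 5.23 (SE 0.67). The monocyte-attracting chemokine Ccl2 rose by 4.65 (SE 0.22) and the interferon-inducible GTPase Igtp by 4.67 (SE 0.50). Adjusted p of these 6 genes ran from 2.12e-06 to 0.000678, and Cxcl10 and Ccl2 were above background on 1 saline array. Of genes not above background on any saline array, Ptx3, a pattern recognition molecule, was at least 49.5-fold higher with LPS (adjusted p = 3.82e-06). Csf3, the granulocyte colony-stimulating factor, was at least 22.4-fold higher (adjusted p = 2.57e-05) and the chemokine Ccl5 at least 18.3-fold (adjusted p = 1.66e-05). Ubd, a ubiquitin-like modifier, was at least 7.87-fold higher (adjusted p = 0.00501) and Cxcl2 at least 7.50-fold (adjusted p = 3.16e-06). After Tcf15, the falls were led by the methyltransferase Inmt at -2.59 (SE 0.42), Fam78a at -2.45 (SE 0.31), the scaffold protein Slc9a3r2 at -2.44 (SE 0.56). Next came the serine protease Htra3 at -2.43 (SE 0.52), and Ky (above background on 1 LPS array), C1qtnf9 and Cxcl12 at -2.38 each (SE 0.25, 0.26 and 0.36), with adjusted p from 0.000205 to 0.0138. Other probes of Slc9a3r2 gave -1.47 and -0.56 and those of Cxcl12 -2.44, -0.14 and -0.43. Another probe above background gave -1.22 for Htra3, 3.28 for Cxcl9, 2.91 for Csf3 and 1.69 for Ptx3, so the bounds hold for the brightest probe only. In 2086 genes (23.5%) every LPS array lay on the same side of every saline array, where chance arrangement of the arrays gives 2.86%; 1566 of the called genes were among them and 165 were not. A further 527 unnamed probes passed, 261 higher and 266 lower.

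Scan day, slide series and a mark, redip, on 4 arrays were each tried as a block and within batches; the meaning of that mark is not given in the sources used here. With scan day as a block 1388 genes passed and 1272 of the 1731 kept their call. Within the first scan day (LPS 2 to 4, saline 3 and 4) 445 passed. Of 444 genes called within that day and measured on the second day's LPS 1 and saline 2, 432 (97.3%) had the same sign there. The third day held saline 1 only. With the slide series as a block 759 genes passed, the first series holding LPS arrays only, so that the estimate rests on LPS 1; within the second series (LPS 1 and all saline arrays) 828 passed, the spread among LPS arrays not being measured there. With the redip mark as a block 1576 passed; the 4 marked arrays alone gave 1290 and the 4 unmarked ones 72. Leaving out LPS 2 gave 1104 genes and leaving out saline 2 gave 1143, with 483 and 518 lower, and leaving out LPS 4 gave 495 lower. Under median scaling of each array in place of quantile normalization, 23.5% of 1484 called genes were higher in place of 49.9%. The median change of all tested genes was then -0.35 against -0.05. Median scaling over the tested probes gave 51.6% of 1536 called genes higher.

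**Figure D1:**
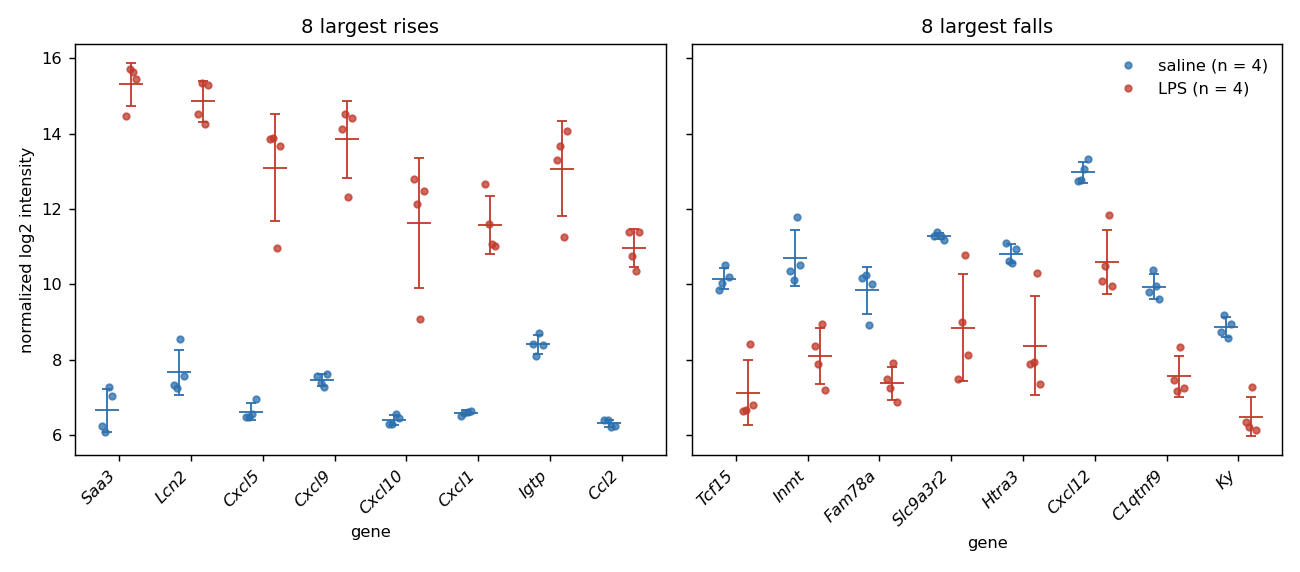
Normalized log2 intensity of the 8 genes with the largest rise and the 8 with the largest fall. Ranked were called genes whose groups did not overlap and that were above background on some array of each group. Points are single arrays (blue saline and red LPS, n = 4 each), with group mean (dash) and SD (bars). Saa3 averaged 15.32 with LPS against 6.66 with saline, and Tcf15 averaged 7.13 against 10.15.

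Inflammatory signalling genes were broadly higher with LPS. Among 23 measured cytokines and chemokines 21 rose and 1, Ccl6, fell, with the same counts adjusted over the list alone. The median log2 change was 1.52 (1.47 with members near background at their bound; camera adjusted p = 8.33e-19). Il6 and Il1b, classical inflammatory cytokines, were not above background on any saline array and were at least 1.94-fold (adjusted p = 0.00338) and at least 2.01-fold higher (adjusted p = 0.000827). Tnf rose by 0.83 (SE 0.23, adjusted p = 0.0295; above background on 2 saline arrays). Of 29 Toll-like receptor and NF-kB genes 22 rose and none fell (23 adjusted over the list alone; median 1.37, or 1.33 at the bound; camera adjusted p = 5.64e-18). The feedback inhibitors Tnfaip3 (4.43, SE 0.19, adjusted p = 9.17e-07) and Socs3 (4.19, SE 0.26, adjusted p = 1.07e-05) were among them. Cd14, the LPS co-receptor, rose by 1.15 (SE 0.21, adjusted p = 0.00517) and Tlr4, the LPS receptor, by 0.75 (SE 0.19, adjusted p = 0.0222). The call of Ccl6 ended without LPS 1, LPS 2, LPS 4, saline 2 or saline 3 (adjusted p 0.0538 to 0.0825). That of Tnf ended without LPS 2 or any 1 saline array (0.0552 to 0.0752), and that of Tlr4 without LPS 2, LPS 4, saline 1 or saline 2 (0.0527 to 0.0657). Median scaling ended the calls of Cd14 (0.0522), Tnf (0.0694) and Tlr4 (0.0957), and the scan day block those of Tnf (0.0947) and Ccl6 (0.0551). Under median scaling over the tested probes Ccl6 was at -0.33 (0.272).

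Interferon target genes rose together on every LPS array, least on LPS 3. Of 25 interferon-stimulated genes 24 rose and none fell (24 adjusted over the list alone). The median log2 change was 2.41 and a camera adjusted p of 2.42e-23 (adjusted p = 0.0923 with an estimated correlation). Oasl1 and Ifit3, antiviral effectors, rose by 3.86 (SE 0.37, adjusted p = 0.000143; above background on 1 saline array) and 3.48 (SE 0.39, adjusted p = 0.00034; another Ifit3 probe gave 1.34). Of 30 interferon-gamma, guanylate-binding and antigen processing genes 24 rose and 1, the MHC class II chain H2-Aa (-0.72, SE 0.13, adjusted p = 0.0051), fell (26 and 1 adjusted over the list alone). That list had a median of 2.17 and a camera adjusted p of 8.3e-18 (adjusted p = 0.15 with an estimated correlation). The mean of the interferon-gamma list, relative to saline, was 1.26 on LPS 3 and 2.53 to 2.67 on the other LPS arrays, and that of the interferon-stimulated list 1.55 against 2.47 to 2.65. Taking each spot's mean in place of its median brightness, an alternative chosen after the data were seen, ended the call of H2-Aa (-0.37, 0.148).

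Acute phase and glucocorticoid-responsive genes also rose. In the acute phase and metal binding list 19 of 22 rose and none fell (20 adjusted over the list alone), with a median of 2.23 and a camera adjusted p of 4.13e-19. Of 19 glucocorticoid-responsive genes 13 rose and none fell (14 adjusted over the list alone; median 1.09, camera adjusted p = 1.67e-12). The 6 that did not pass were Dusp1, Hif3a, Klf15, Slc38a2, Sult1a1 and Tsc22d3. Among those that rose were Lcn2 and the metallothionein Mt2 (3.84, SE 0.29, adjusted p = 3.29e-05), both also in the acute phase list. The acute phase, glucocorticoid, cytokine and Toll-like receptor lists are the 4 that passed camera with an estimated correlation, at adjusted p of 0.0293, 0.0473, 0.0128 and 0.0293. Of 29 AP-1 and MAP kinase genes 10 rose and none fell (11 and 2 adjusted over the list alone; median 0.26, camera adjusted p = 5.66e-05; adjusted p = 0.128 with an estimated correlation). They were led by Zfp36, an mRNA decay factor (3.47, SE 0.31, adjusted p = 8.36e-05), and the kinase Map3k6 (2.90, SE 0.15, adjusted p = 3.81e-06).

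Genes of mitochondrial energy metabolism had small negative medians, and few of them fell individually. Under median scaling the medians of oxidative phosphorylation, tricarboxylic acid and fatty acid genes were -0.56, -0.60 and -0.53, that scaling having lowered all genes. The 45 oxidative phosphorylation genes had a median of -0.24 (camera adjusted p = 0.00848; adjusted p = 0.123 with an estimated correlation). Of these only Cox5a, Atp5pb and Ndufb3 fell and none passed when adjusted over the list alone. Among 33 genes of the tricarboxylic acid cycle and branched-chain amino acid breakdown Fh1, Bdh1 and Ppm1k fell, none rose and 2 fell adjusted over the list alone (median -0.20, camera adjusted p = 0.00816; adjusted p = 0.23 with an estimated correlation). Fh1, the fumarase, changed by -0.94 (SE 0.21, adjusted p = 0.0136) and Bdh1, a ketone body enzyme, by -0.66 (SE 0.12, adjusted p = 0.00517). Fatty acid uptake and oxidation as a list did not pass camera (29 genes, median -0.20, adjusted p = 0.182). Eci1 (-1.06, SE 0.23, adjusted p = 0.00999) and Ech1 (-1.01, SE 0.27, adjusted p = 0.0272), auxiliary enzymes of beta-oxidation, fell, 1 of them adjusted over the list alone. Cpt1b, Cd36 and Lpl had log2 changes of -0.35 (SE 0.33, adjusted p = 0.49), -0.62 (SE 0.25, adjusted p = 0.121) and 0.25 (SE 0.13, adjusted p = 0.219; another Lpl probe gave 0.08). The oxidative phosphorylation list lost its call under cyclic loess (0.0867) and, like the tricarboxylic acid list (0.0992), within the first scan day (0.105). Omitting LPS 2, LPS 4, saline 1, saline 2 or saline 3 ended the call of Ech1 (0.0599 to 0.081). Omitting LPS 1 or saline 3 ended that of Cox5a (0.0506 to 0.0539), and omitting LPS 2, LPS 3, LPS 4, saline 1 or saline 2 that of Atp5pb (0.0571 to 0.0968). With each spot's mean brightness Ech1 was at -0.16 (0.283), Fh1 at -0.38 (0.114), Cox5a at -0.32 (0.0529) and Atp5pb at -0.50 (0.116), all without a call. Within the first scan day Fh1 was at -0.48 (0.119), Atp5pb at -0.42 (0.128) and Eci1 at -0.67 (0.164), also without one. With replicate number as a block Cd36 passed (0.0465), while 3 other named genes lost their call. The change of Cpt1b ran from -0.67 without LPS 4 to -0.16 without LPS 3.

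Regulators of lipid use changed in both directions. Of 37 PPAR, PGC-1, ERR and lipid storage genes 6 rose and 8 fell (7 and 9 adjusted over the list alone). The list did not pass camera (median 0.01, mean -0.03, adjusted p = 0.905; median -0.36 under median scaling). Angptl4, an inhibitor of lipoprotein lipase, rose by 3.53 (SE 0.30, adjusted p = 6.5e-05) and Pdk4, an inhibitory kinase of pyruvate dehydrogenase, by 2.19 (SE 0.39, adjusted p = 0.00421). G0s2, an inhibitor of adipose triglyceride lipase, fell by 2.34 (SE 0.41, adjusted p = 0.00421), and the coactivator Ppargc1b fell by 1.85 (SE 0.30, adjusted p = 0.00261). Ppargc1a had a change of -0.73 (SE 0.18, adjusted p = 0.0221), Pparg of 0.57 (SE 0.14, adjusted p = 0.0171), and Ppara of -0.23 (SE 0.13, adjusted p = 0.251). Klf5 was at least 1.36-fold higher (adjusted p = 0.00375; dim on every saline array). The call of Ppargc1a ended without LPS 2, LPS 4, saline 1 or saline 2 (0.0502 to 0.0678), and that of Pparg, whose other probe above background gave 0.07, under median scaling (0.17, 0.586). In the glucose uptake and glycolysis list, which did not pass (28 genes, median -0.13, adjusted p = 0.643), Pfkfb3, Slc16a3 and Slc2a1 rose and Pfkfb2, Aldoa and Slc2a4 fell (3 and 3 adjusted over the list alone). Pfkfb3, an activator of glycolysis, rose by 2.93 (SE 0.25, adjusted p = 6.5e-05) and its isoform Pfkfb2 fell by 1.07 (SE 0.17, adjusted p = 0.00258). The call of Aldoa ended without any 1 array other than LPS 3 (0.0506 to 0.109), and that of Slc16a3 under median scaling (0.0505).

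**Figure D2:**
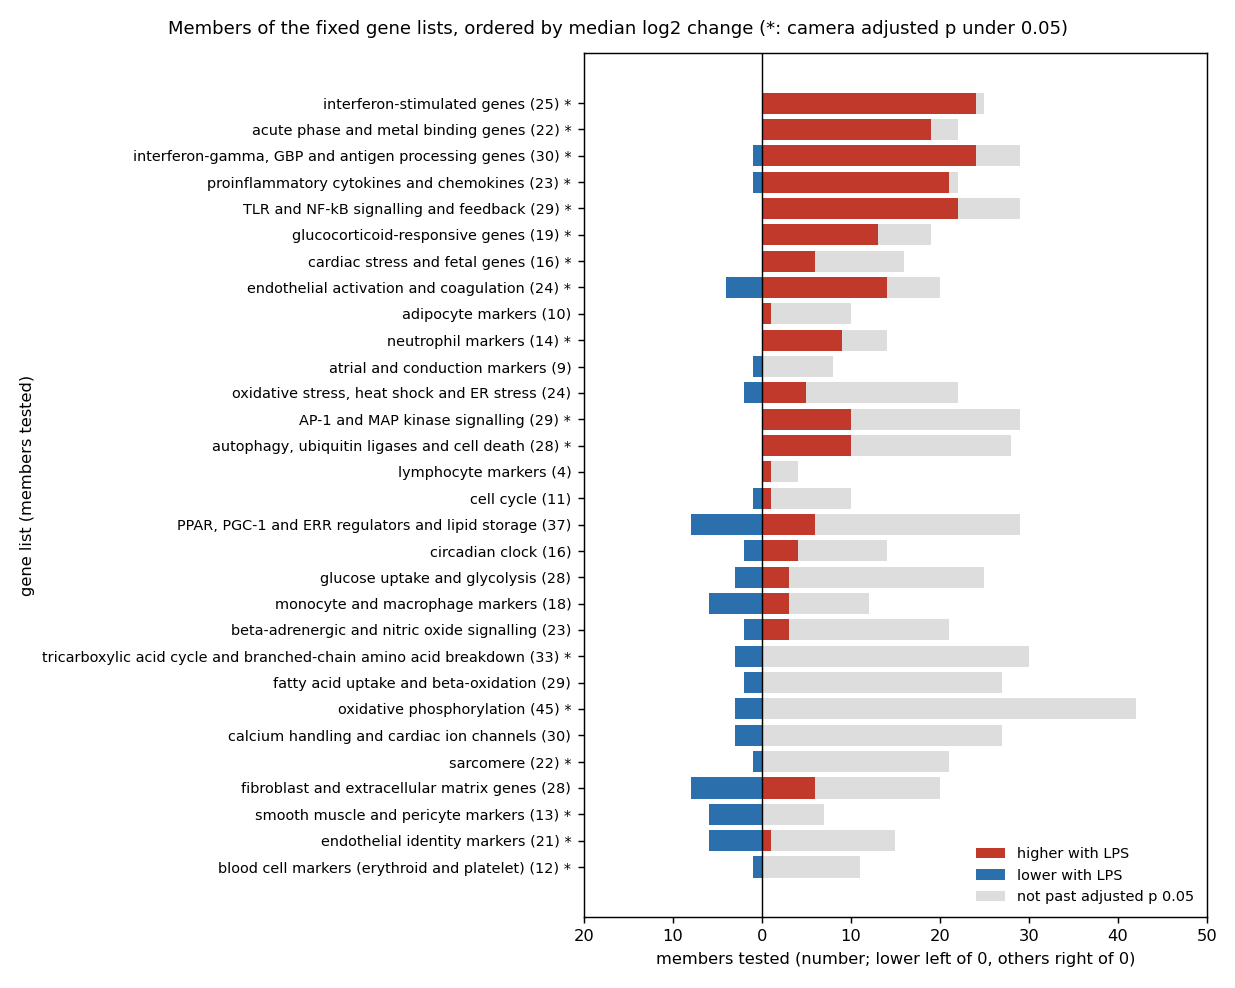
Number of measured members of each of the 30 gene lists that were higher (red, right of 0), lower (blue, left of 0) or not past an adjusted p of 0.05 (grey) with LPS, ordered by median log2 change. Interferon-stimulated genes had 24 higher of 25, the oxidative phosphorylation list 3 lower of 45, and 17 lists, starred, passed camera.

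The sarcomere list had a negative median, and 1 of its members fell. Of 22 sarcomere genes only the chaperone Cryab (-0.94, SE 0.27, adjusted p = 0.0357) passed, and none adjusted over the list alone. The median was -0.32 (camera adjusted p = 0.00362; adjusted p = 0.345 with an estimated correlation). Myh6, the main adult myosin heavy chain, had a log2 change of -0.85 (SE 0.30, adjusted p = 0.0732; saturated on 1 saline array), Myh7 of 0.00 (SE 0.51, adjusted p = 0.999; another probe gave -0.42) and the calcium pump Atp2a2 of -0.13 (SE 0.14, adjusted p = 0.566; saturated on 2 saline arrays; another probe gave -0.46). Among 30 calcium handling and ion channel genes Jph2, which anchors calcium release units, fell by 0.93 (SE 0.18, adjusted p = 0.00683; another probe gave -0.36), with Abcc9 and Kcnj8, subunits of one potassium channel and also pericyte markers (3 adjusted over the list alone). The list did not pass (median -0.28, adjusted p = 0.0791), but it did without the dim-probe filter (0.0119), without LPS 1 (0.0261) or saline 3 (0.03995), under median scaling over the tested probes (0.0311) and by fry (0.0233). The call of Cryab ended without LPS 2, LPS 3, LPS 4, saline 2, saline 3 or saline 4 (0.0685 to 0.101) and its change was 0.04 when each spot's mean brightness was used. That of Abcc9 ended without LPS 2, LPS 4, saline 2, saline 3 or saline 4 (0.0616 to 0.0723). The sarcomere list lost its call under median scaling (0.051), with mean spot brightness (median -0.15, 0.104) and with the slide series as a block (0.548). Myh6 passed without background correction (-0.74, 0.0449) and with the atrial covariate (-0.95, 0.041). Leaving out 1 array moved its change between -1.01 (without saline 3) and -0.52 (without saline 1).

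Of 16 cardiac stress and fetal genes 6 rose, none fell and 10 did not pass (8 higher adjusted over the list alone), with a median of 1.02 (camera adjusted p = 9.68e-05; adjusted p = 0.281 with an estimated correlation). The muscle ankyrin protein Ankrd2 rose by 3.71 (SE 0.70, adjusted p = 0.00563; above background on 1 saline array) and the cell cycle inhibitor Cdkn1a by 3.36 (SE 0.30, adjusted p = 8.36e-05; another probe gave 2.14). Natriuretic peptide gene Nppb had a change of 0.13 (SE 0.57, adjusted p = 0.892), which ran from -0.48 without LPS 1 to 0.60 without LPS 3 and passed at 1.97 (0.0159) within the second slide series, where LPS 1 is the only LPS array. The list mean was 2.34 on LPS 1 and 0.36 on LPS 3. The list median was 0.73 within the first scan day. With the slide series as a block, where the estimate rests on LPS 1, it was 2.29. In beta-adrenergic and nitric oxide signalling (23 genes; 3 rose and 2 fell, 3 and 4 adjusted over the list alone; median -0.14, adjusted p = 0.905) the cAMP phosphodiesterase Pde4b rose by 2.38 (SE 0.42, adjusted p = 0.00421), and Gch1 and Ass1 also rose. The phosphodiesterase Pde4a had -0.96 (SE 0.22, adjusted p = 0.0143; other probes gave -0.59 and 0.47) and the receptor Adrb1 -0.66 (SE 0.16, adjusted p = 0.018). Adrb3 and Nos2 were not above background on enough arrays to be tested, and Nppa and Ly6g were not analysed here. The call of Adrb1 ended without LPS 2 or LPS 4 (0.0552 to 0.0588) and with scan day as a block (0.0617), and that of Gch1 under median scaling (0.0714).

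Endothelial activation genes held more rises than falls, and endothelial identity and smooth muscle markers more falls than rises. Of 24 endothelial activation and coagulation genes 14 rose and 4 fell (15 and 4 adjusted over the list alone; median 0.94, or 0.77 at the bound; camera adjusted p = 2.59e-06; adjusted p = 0.128 with an estimated correlation). The leukocyte adhesion molecule Icam1 rose by 4.27 (SE 0.31, adjusted p = 2.5e-05) and Selp was at least 7.27-fold higher (adjusted p = 3.99e-05). The 4 that fell were Pdgfb, Ptgs1, F3 and Esm1; Ptgs1 fell by 0.73 (SE 0.16, adjusted p = 0.0116; above background on 1 LPS array). Of 21 endothelial identity markers 6 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 0.000877; adjusted p = 0.273 with an estimated correlation). Examples are Egfl7 at -2.13 (SE 0.31, adjusted p = 0.00155), the apelin receptor Aplnr at -2.04 (SE 0.24, adjusted p = 0.000396; above background on 3 LPS arrays) and Rgcc at 1.36 (SE 0.22, adjusted p = 0.00266). Of 13 smooth muscle and pericyte markers 6 fell and none rose (8 adjusted over the list alone; median -0.46, camera adjusted p = 0.000836; adjusted p = 0.128 with an estimated correlation). Among them were Smtn (-1.24, SE 0.24, adjusted p = 0.00659; another probe gave -0.63) and Notch3 (-0.80, SE 0.16, adjusted p = 0.00695). The call of Pdgfb ended without LPS 2, LPS 4, saline 2, saline 3 or saline 4 (0.064 to 0.0749).

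Markers of blood-derived cells went different ways. Of 14 neutrophil markers 9 rose and none fell (10 adjusted over the list alone; median 0.82, or 0.74 at the bound; camera adjusted p = 7.5e-09; adjusted p = 0.0923 with an estimated correlation). The formyl peptide receptor Fpr2 rose by 3.43 (SE 0.26, adjusted p = 3.31e-05; above background on 2 saline arrays) and the calgranulin S100a8 by 3.12 (SE 0.36, adjusted p = 0.000388; above background on 3). Requiring signal above background on all 8 arrays ended that list's call (median 0.19, 0.242). That filter kept only Itgam, Mmp9 and Prtn3 and removed all 9 markers that rose, each of them dim on at least 1 saline array, so the change itself decided which members stayed. The main filter has the same weakness, since it can keep a marker bright on the 4 LPS arrays alone. Of 29 neutrophil markers listed, 26 were on the array and 14 passed it, 5 of them with a change given as a bound. Of 18 monocyte and macrophage markers 3 rose and 6 fell (5 and 8 adjusted over the list alone; median -0.14, camera adjusted p = 0.596). Plac8 was at least 3.36-fold higher (adjusted p = 0.00116) and the Fc receptor chain Fcer1g rose by 1.75 (SE 0.23, adjusted p = 0.000713). The lysozyme Lyz2 fell by 1.18 (SE 0.25, adjusted p = 0.00935) and the complement chain C1qc by 1.20 (SE 0.31, adjusted p = 0.0234). Of 28 lymphocyte markers 4 were measured and Zap70, a T cell kinase, rose (0.58, SE 0.15, adjusted p = 0.0235; 1 adjusted over the list alone; median 0.07 but -0.05 under median scaling, adjusted p = 0.423). Erythroid and platelet markers were lower as a list (12 genes, median -0.55, camera adjusted p = 0.0244; adjusted p = 0.517 with an estimated correlation). Only the globin Hbb-bt passed (-1.24, SE 0.37, adjusted p = 0.0439) and none adjusted over the list alone. That list's call ended without LPS 3 or saline 3 (0.0901 to 0.13), under median scaling (0.051), with the slide series as a block (0.137), by fry (0.133) and on the arrays marked redip alone (0.105). Its median was -0.30 without saline 3. The call of C1qc ended without LPS 2, LPS 4, saline 1 or saline 2 (0.0566 to 0.0666) and within the first scan day (-0.59, 0.11). That of Zap70 ended without saline 1, saline 2 or saline 4 (0.056 to 0.0617), with the scan day block (0.0636) and under median scaling (0.0771). That of Hbb-bt ended without LPS 1, LPS 2, LPS 3, LPS 4, saline 2 or saline 3 (0.0714 to 0.109).

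Extracellular matrix genes changed in both directions, 6 higher and 8 lower of 28 (6 and 9 adjusted over the list alone; median -0.42, camera adjusted p = 0.237). The matrix metalloproteinase Mmp3 rose by 2.07 (SE 0.20, adjusted p = 0.000144) and the collagen cross-linking enzyme Lox by 1.97 (SE 0.19, adjusted p = 0.000148), while the matrix protein Fbln2 fell by 1.38 (SE 0.22, adjusted p = 0.00221). Other probes of Mmp3 and Fbln2 gave 1.37 and -0.55. The matrix median ran from -0.53 without saline 3 to -0.27 without LPS 4. Atrial and conduction markers did not pass as a list (9 genes, median 0.58, adjusted p = 0.695), and of its members Clec3b fell (-0.86, SE 0.14, adjusted p = 0.00317; above background on 2 LPS arrays; 1 adjusted over the list alone). Their list mean ranged within groups from -1.75 on LPS 4 to 1.29 on LPS 3 and from -1.43 on saline 2 to 1.52 on saline 1. Of 10 adipocyte markers Fasn, the fatty acid synthase, rose (1.54, SE 0.21, adjusted p = 0.00103; 1 adjusted over the list alone). That list had a median of 0.90 (adjusted p = 0.0791) and a mean of -0.39 on LPS 4 against 1.17 to 1.21 on the other LPS arrays. Without LPS 4 the atrial (0.0433; median 0.95) and adipocyte (0.000612; median 1.30) lists passed, and without saline 2 the atrial median was 0.14. The adipocyte list also passed under median scaling (0.0222), without the dim-probe filter (0.00216), with the atrial mean as a covariate (0.0252), within the second slide series (0.01185) and on the unmarked arrays alone (0.000108). Median scaling ended the call of Fasn (0.0583).

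**Figure D3:**
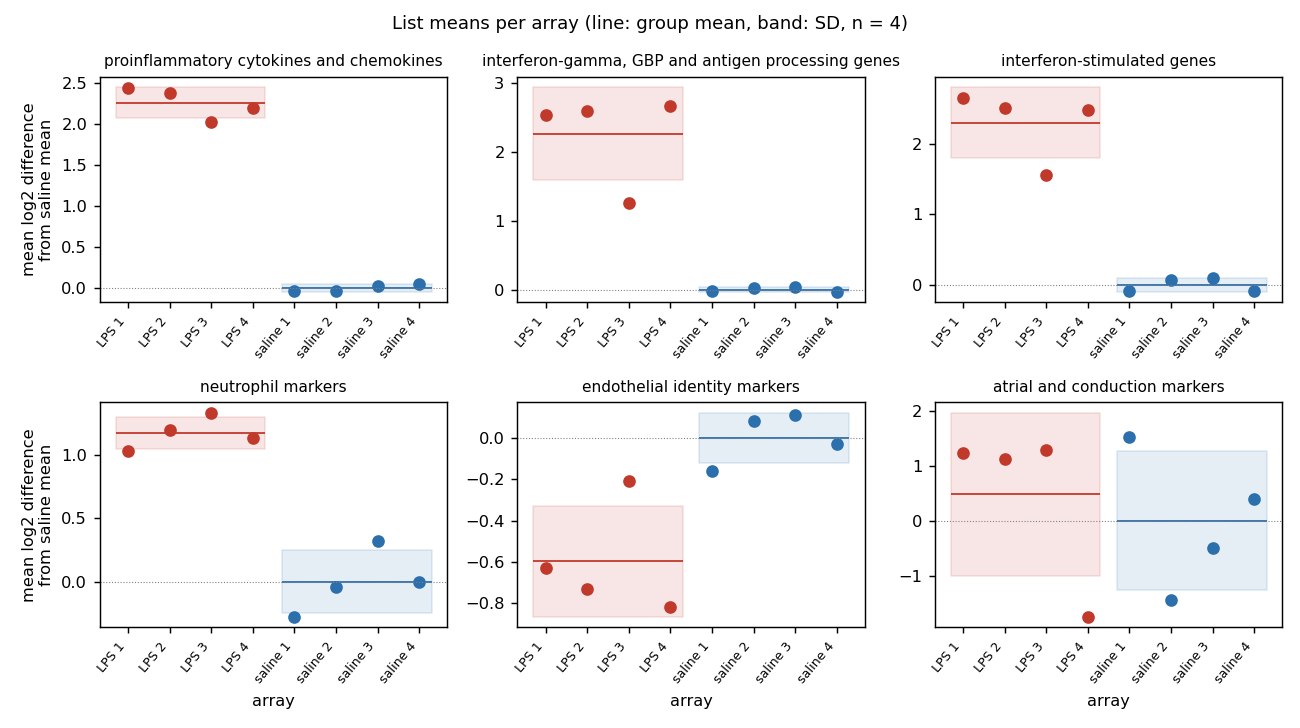
Mean log2 difference from the saline mean of 6 gene lists on each array (red LPS, blue saline), with group mean (line) and SD (band), n = 4 per group. Interferon-gamma genes reached 1.26 on LPS 3 and 2.53 to 2.67 on the other LPS arrays, and atrial markers ranged from -1.75 to 1.29 within the LPS group.

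Clock, stress and cell death genes completed the lists. Of 16 circadian genes 4 rose and 2 fell (4 and 3 adjusted over the list alone). Arntl, a core clock activator, rose by 1.28 (SE 0.18, adjusted p = 0.00123) and Per1 by 1.22 (SE 0.20, adjusted p = 0.00317), while Per3 fell by 1.25 (SE 0.21, adjusted p = 0.00288) and Tef fell by 1.16 (SE 0.21, adjusted p = 0.00434). Other probes of Per3 and Tef gave -0.75 and -0.42. That list did not pass (adjusted p = 0.708), and its median of -0.05 differed in sign from its mean of 0.04 and from the test. In oxidative, heat shock and ER stress (24 genes; 5 rose and 2 fell, 8 and 4 adjusted over the list alone; median 0.36, -0.08 under median scaling; adjusted p = 0.0791) the haem oxygenase Hmox1 rose by 4.24 (SE 0.85, adjusted p = 0.00748), with saline 3 at 12.45 and the other saline arrays at 7.99 to 9.04. Chac1, a glutathione-degrading enzyme, rose by 2.36 (SE 0.22, adjusted p = 0.000112), and the transcription factor Ddit3 fell by 1.08 (SE 0.15, adjusted p = 0.00134). Of 28 autophagy, ubiquitin ligase and cell death genes 10 rose and none fell (10 adjusted over the list alone; median 0.26 but -0.09 under median scaling; camera adjusted p = 0.00144; adjusted p = 0.169 with an estimated correlation). The largest rises were those of the inflammatory caspase Casp4 (1.72, SE 0.27, adjusted p = 0.00197; above background on 1 saline array) and the muscle ubiquitin ligase Fbxo32 (1.62, SE 0.39, adjusted p = 0.0173; another probe gave 0.98). In 11 cell cycle genes Ccne1 rose and Mcm5 fell (2 and 1 adjusted over the list alone; median 0.05, -0.18 under median scaling; adjusted p = 0.695). The call of Fbxo32 ended without LPS 2, LPS 4, saline 1 or saline 2 (0.0502 to 0.0533) and that of Ccne1 without the same arrays (0.064 to 0.0742). That of Mcm5 ended without any 1 array (0.0641 to 0.108), and under median scaling over the tested probes it was at -0.11 (0.658). Within the first scan day Hmox1 was at 2.76 (0.155). With the slide series as a block the cell death list lost its call (0.0571), and without saline 3 its median was 0.41.

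With the slide series as a block, where LPS 1 is the only LPS array in the series of the saline ones, the calls of these genes ended: Inmt (0.0778), Htra3 (0.073), Ubd (0.07525), Hmox1 (0.0739), Pdk4 (0.0645), Per1 (0.0793), Per3 (0.0579), Fbln2 (0.105), Smtn (0.123), Plac8 (0.059), Rgcc (0.0652) and Lyz2 (0.0546). So did those of Bdh1, Cox5a, Gch1, Clec3b, Mcm5, H2-Aa, Tef, Adrb1, Jph2, Ccl6, Ppargc1a, C1qc, Pde4a, Hbb-bt, Tnf, Zap70, Atp5pb, Abcc9, Aldoa, Tlr4, Slc16a3, Fbxo32, Ech1, Ccne1 and Cryab, with adjusted p from 0.0533 to 0.752.

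In all, 17 of the 30 lists passed camera, 11 higher and 6 lower. By fry 19 passed: it gained fatty acid oxidation (0.0459), calcium handling (0.0233) and oxidative and ER stress (0.01115), and lost the erythroid and platelet list (0.133). The oxidative and ER stress list also passed under median scaling with a negative median (0.0492), with mean spot intensity (0.048) and on the arrays marked redip (0.0469). Fatty acid oxidation passed within the second slide series (0.049), and the matrix list with the atrial covariate (0.041). All 17 kept the sign of their median with scan day as a block and within the first scan day, and 16 did so under median scaling, the cell death list being the exception. Median scaling moved the medians of sarcomere (-0.66), calcium handling (-0.67), endothelial identity (-0.92), smooth muscle (-0.72), matrix (-0.72), glycolysis (-0.46), beta-adrenergic (-0.49), macrophage (-0.49) and circadian genes (-0.24) further down. It lowered those of AP-1 (0.04), endothelial activation (0.53), cardiac stress (0.66), glucocorticoid-responsive (0.68) and atrial genes (0.36). No named gene that passed changed sign under median scaling, median scaling over the tested probes, cyclic loess or without background correction.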

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

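Both tests of dilution of LPS 3, the 3 tests on atrial markers and the separate count of splits with 2 LPS arrays on each side were chosen only after the result was seen. In 22 of 276 groups of 4 arrays (7.97%), 1 array lay far from the other 3; chance flags about 1 in 20 groups.

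LPS 3 differed from the other LPS arrays, mostly by lying between them and saline. On the first principal component, the main axis of difference among the arrays (62.9% of variance), the other LPS arrays lay at 35.26 to 35.76. The saline arrays lay at -33.99 to -24.74 and LPS 3 at 11.94. It was lower than the other LPS arrays in the list means of interferon-gamma genes (1.26 against 2.53 to 2.67), interferon-stimulated genes (1.55 against 2.47 to 2.65) and Toll-like receptor genes (1.13 against 1.41 to 1.46). The same held for the log2 levels of Csf3 (9.61 against 11.38 to 11.46), Cxcl5 (10.97 against 13.68 to 13.89) and Socs3 (10.49 against 11.55 to 11.69), and Tcf15 was higher (8.41 against 6.63 to 6.79). The means of neutrophil markers (1.33 against 1.03 to 1.19) and glucocorticoid-responsive genes (1.77 against 1.68 to 1.75) were highest on LPS 3. For the glucocorticoid list the margin was narrow. Of its 10 members called at least 2-fold higher without LPS 3, 0 exceeded all other LPS arrays there. Their median rise was 65.8% of that of the other LPS arrays. Of 6 such neutrophil markers 3 exceeded all other LPS arrays.

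Scaling between arrays was tested for this pattern. LPS 3 stayed below the next LPS array in the interferon-gamma mean by 1.13 under median scaling and 1.35 under cyclic loess. These gaps argue against scaling. Without background correction, with quantile normalization kept, the gap was 1.32. Dilution with RNA of an untreated heart would give every list the same share of the response of the other LPS arrays. The median share was 53.5% for cytokines, 21.5% for interferon-gamma genes, 91.3% for acute phase genes and 142% for 6 neutrophil markers. The cytokine and interferon-gamma lists lay 32 points apart (permutation p = 5e-04, 10000 resamples, treating genes as independent), which argues against dilution as the whole cause. LPS 3 exceeded all other LPS arrays for 5.14% of 953 genes called higher without it, a value that decides neither way. A response of that mouse that differs between gene groups may be a candidate explanation and was not tested.

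Atrial markers differed within both groups. Their list mean was -1.75 on LPS 4 against 1.13 to 1.29 on the other LPS arrays, where the adipocyte mean (-0.39 against 1.17 to 1.21), the matrix mean (-0.48 against -0.05 to -0.02) and the log2 level of Gsn (11.75 against 12.84 to 12.92) were low too. On saline 2 the atrial mean was -1.43.

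Defective single spots were tested as the source: 7 of 9 atrial members were lowest on the same pair, LPS 4 and saline 2. A permutation test that placed members independently over all pairs gave p = 1e-04, the smallest that 10000 resamples can give, which argues against them. With the atrial mean as a covariate 89.2% of called genes kept their call, which argues against unequal atrial share as the source of most LPS calls; whether the response varies with that share was not tested. The members' deviations had a mean pairwise correlation of 0.79, above the 0.14 that bounds 95% of random lists, so different amounts of atrial tissue in the heart pieces may account for the pattern.

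Control probes whose identifiers mark viral genomes gave a signal outside the gene probes. Of 53 tested, 15 were higher with LPS and none lower in limma, by 0.83 to 1.90 on the log2 scale (median 1.41, SE 0.23), and all 15 had every LPS array above every saline array. The 15 came from 8 viral genomes, so they may not be 15 separate signals. No tested probe of the other viral genomes passed (lowest adjusted p = 0.146 in limma), and some probes of these 8 did not pass either. Whether the 8 genomes share sequence was not tested. Of 255 other control probes 0 passed.

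Chance was tested on these viral-genome probes by regrouping the arrays: 1 of 35 splits gave as many, the real one. The highest other count was 1, which argues against chance as far as 35 splits can show. The other splits mixed LPS and saline arrays, which widened the spread within their groups. A general rise of bright probes was tested with 10000 random lists of gene probes of the same brightness. The median of all 53 was 0.47, at percentile 100 of those lists, whose medians lay near 0.05 at their upper end. These values argue against a rise shared by gene probes of that brightness. The percentile treats the 53 probes as independent. Several came from the same viral genome and may move together, so it does not measure how unusual they are as a set. Scaling between arrays stays open: 0 passed under median scaling in limma (12 at an unadjusted p of 0.05; median 1.01, SE 0.29, lowest adjusted p = 0.0639), the change being smaller and its error larger, and 15 under cyclic loess. Mouse transcripts that share sequence with these probes may be a source, which was not tested.

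The gene count of 1731 was reached in 1 of 35 splits of the arrays into 4 and 4, the real one. The highest other count was 0, which argues against chance as far as 35 splits can show. Every other split mixed LPS and saline arrays, so the LPS difference widened the spread within its groups and kept its count low. Regrouping does not address the slide series, the first of which held LPS arrays only. The 17 lists were reached in 6 of 35 splits, with 18 the highest other, so over all splits chance cannot be excluded for that count with the preset correlation. The 5 other splits all kept 3 LPS arrays together and so hold part of the LPS difference. The 18 splits with 2 LPS arrays on each side gave at most 8 lists in camera, and 0 of them reached 17. The highest split set LPS 1, LPS 2, LPS 3 and saline 4 against the rest. With an estimated correlation the real split gave 4 lists and the highest other 0.

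Other single arrays lay apart as follows. On LPS 1, log2 levels were 6.93 for Aplnr (others 6.60 to 6.65) and 8.85 for Chac1 (9.73 to 9.82), and 21 spots were saturated (7 to 9). On saline 3 they were 7.32 for Ccl6 (6.72 to 6.80), 14.21 for Cox5a (13.88 to 13.91), 7.16 for Lox (6.80 to 6.84) and 12.41 for Mt2 (11.01 to 11.21). Saline 1 had 8.66 for Pfkfb2 (8.10 to 8.16) and a sarcomere mean of 0.25 (-0.10 to -0.05). Saline 2 had 6.97 for Ptgs1 (7.19 to 7.23) and 11.08 for Smtn (10.31 to 10.42).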

How the results depend on the processing

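The settings using mean spot intensity, the arrays with or without the redip mark, the second slide series, LPS 3 and saline 1 both left out, the atrial covariate and median scaling over tested probes were chosen only after the result was seen. Over the settings, 2671 of the comparisons of named genes kept direction and side of the threshold, 418 lost the call, 4 gained it and 1 reversed; for lists 879 kept it, 31 lost it and 19 gained it. The reversed value was Cryab, 0.04 under mean spot intensity. Called genes kept were 1090 (63.0%) under median scaling, 1527 under cyclic loess, 1272 with the scan day block and 657 with the slide series block.

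Median scaling gave 349 genes higher, 260 at least 2-fold higher and 519 at least 2-fold lower. Over the tested probes it gave 792 genes higher, 435 at least 2-fold higher and 194 at least 2-fold lower. Offset 16 gave 289 at least 2-fold lower. The first scan day alone, with fewer arrays, gave 445 genes, 289 higher and 156 lower, 244 and 81 at least 2-fold. The slide series block gave 759 (490 higher, 269 lower), and the second slide series alone, whose single LPS array is assumed to vary like saline, 828 (545, 283). A plain t statistic gave 1100, with 501 lower and 114 at least 2-fold lower. Camera with an estimated correlation gave 4 lists. Leaving out LPS 3 and saline 1 gave 271 at least 2-fold lower, the marked arrays alone 306. The unmarked arrays alone gave 72 genes, 69 higher and 3 lower, all at least 2-fold. The value table gave 1207 of 34945 probes, 325 lower, with 878 and 324 at least 2-fold; gene and list results were not run on it because no identifiers matched. The cause of these differences was not tested. Median scaling, offset 16 and the plain t statistic used all arrays. The marked and the unmarked sets held equally many arrays yet gave 1290 and 72 genes, so fewer arrays cannot account for all differences.

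Leaving out 1 array at a time gave 1104 (without LPS 2) to 2.0e+03 genes (without LPS 3: 953 higher, 1057 lower). Higher genes ran from 621 to 953 and lower ones from 483 to 1057, with 385 to 491 and 124 to 260 at least 2-fold, and 16 to 19 lists. Replicate numbers did not pair arrays (correlations of deviations 0.08, -0.14, 0.09 and -0.08); as a block they gave 1526 genes and 17 lists. Low signal over background (12 to 32) limits what can be seen of dim genes.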

Other observations

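The test of endothelial markers against their own list was chosen only after the result was seen, as were the genes named here. Relative to the list median, 4 of 21 endothelial identity markers were lower and 2 higher after adjustment within the list. Egfl7, Aplnr, Tek and Sox18 lay below it by -1.62, -1.53, -1.30 and -0.90 (adjusted p = 9.03e-06, 0.000107, 0.000107 and 0.00924 in limma), and Rgcc and Robo4 above it by 1.87 and 1.17 (adjusted p = 2.96e-06 and 0.00323).

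The atrial myosin light chain Myl7 had signals over background of 38714, 33989, 24768 and 2 intensity units on LPS arrays 1 to 4, and of 65492 (saturated), 27, 1481 and 13252 on saline arrays 1 to 4. Myl4 had 32968, 11539, 14169 and 57 with LPS and 29092, 86, 626 and 5542 with saline.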
